A study of Arabidopsis thaliana with 40 samples.

How the data were processed

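The deposited table holds 1 column for each of 40 ATH1 arrays and 22810 probe sets. Per the labels, total RNA came from the shoot apex, and genotype, day and replicate number were taken from the sample titles. The unit and the normalization are not stated in the sources used here. The deposited values, from 3.03 to 13.63, were read as log2 signal, because a natural antilog of the highest value, 834443, would exceed the 65535 of a 16-bit scanner. They were used as deposited, without a pseudocount. The lower quartile of the arrays lay between 4.66 and 4.92, and the median of 27 bacterial control probe sets, which no plant transcript matches, lay between 3.60 and 3.78, which serves as the background level. The 64 control probe sets were left out, and 22746 were tested.

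Differences were tested with limma 3.58.1 in R 4.3.3, with a linear model of 20 group means on all 40 arrays (20 residual degrees of freedom), contrasts, and empirical Bayes moderation with an intensity trend. All tests were two-sided. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 within each of 24 contrasts: days 3, 5 and 7 against day 0 in each of 5 genotypes, 5 differences between genotypes in the response from day 0 to day 7, and 4 differences at day 0. Errors beside log2 differences are limma standard errors. An exact permutation test of 2 against 2 arrays cannot go below p = 0.333, so no exact test of single comparisons could pass, and groups of 2 were too small for an outlier test. The 24 contrasts, the threshold, the gene lists, the rule for naming genes and most of the alternatives were chosen before the data were examined.

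Names came from the platform's list of genes per probe set, joined to RefSeq gene names, without coordinates or a genome build. Of the tested probe sets, 13513 (59.4%) list 1 gene, 503 list several and 8730 list none. The 13513 stand for 13350 genes, and 11885 of these probe sets carry only a locus identifier as the symbol. For each contrast, the rule named the 10 called genes with the largest rise and the 10 with the largest fall whose replicate values did not overlap between groups, using the probe set with the highest mean for each gene. Members of the fixed lists are named as well, and the rule also asked for LFY, CO, FT, SOC1, AP1, FUL, FLC and ER, which have no probe set listed. Of 221 genes in 15 lists, 21 were measured, 2 (KIN1 and KIN2) only by a probe set shared with another gene. The members measured, with the number of genes in the list, were UFO, PUCHI and FD of 12 for floral meristem identity, SPL/NZZ of 15 for floral organ identity, AGL24, AGL42 and GI of 10 for the photoperiod pathway and floral promoters, ATC, SMZ and SNZ of 16 floral repressors, SPL16 of 16 in the SPL family, CLV3 and PHV of 17 for shoot meristem maintenance, YUC4 and YAB3 of 19 for organ initiation and polarity, GID1A of 19 for gibberellin, LHCB4.1 and RCA of 17 for photosynthesis as a marker of leaf tissue, COR15A and COR47 of 14 for abiotic stress and PDF1.2A of 10 for defence and senescence. The other 4 lists (cell division, circadian clock, vascular tissue, and epidermis and trichomes) had no measured member.

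Lists with at least 3 measured members and 38 families with at least 6 members (by symbol stem, and the plastid genome) were compared with other genes by camera, with a preset correlation of 0.01 and again with an estimated correlation. Sets of probe sets that changed more than 2-fold in Col or in Ler were tested by fry, which asks whether a set moves on balance in 1 direction. The families and these sets were chosen after the data were seen. The mean, median and camera direction differed in sign for the photoperiod list in Ler at day 7 and in the response differences of co-2 and ft-2 from Ler, and for the floral meristem identity list in the response difference of lfy-12 and Col and between the accessions at day 0.

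The share of the other background's transcripts on each array was estimated from probe sets more than 3 log2 units higher in the other background, and again from separate ones 2 to 3 units higher, with lfy-12 grouped with Col, and co-2 and ft-2 with Ler. This check was added after the data were seen, and tested on simulated data, where a share of 10% was read as 10.1% on a Col array and 9.26% on a Ler array. The separate, weaker probe sets read it as 10.5% and 8.34%. The share was added from the same day means that the estimate divides by. This therefore checks the steps and does not measure the error of the estimate on real arrays.

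The limma steps were tested on simulated data with 200 changed probe sets and the same design. For day 7 against day 0 in Col, 38 of 67 changes of 0.5 log2 units, 65 of 67 of 1 unit and 64 of 66 of 2 units were called, and 4 of 171 calls were false (2.34%). For the difference in response between co-2 and Ler, 13 of 67, 59 of 67 and 66 of 66 were called, and 6 of 144 calls were false (4.17%). The noise was drawn independently for each probe set, without deviations shared across the probe sets of an array. These rates therefore check the steps and do not measure false calls in the deposited data.

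The alternatives fixed in advance were quantile normalization, a filter on the 40% of probe sets with the lowest mean, no intensity trend, the replicate number as a block, only the arrays of the genotypes compared, and leaving out each array in turn. Where this left 1 array in a group, that array was assumed to vary like the other groups. The lower quartile of each array and its ubiquitin contrast (the 3' minus the 5' control probe set) as covariates, the response counted from day 3, replicate numbers crossed between groups, and the alternatives for the sets and for the differences held at all days were added after the data were seen. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.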

Results

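Transcript levels were measured in the shoot apex of Arabidopsis thaliana on 40 arrays, each with 22746 probe sets besides controls. Plants of 5 genotypes grew for 30 days in short days (9 h of light and 15 h of dark) at 21 °C and then moved to long days (16 h of light and 8 h of dark), a change that starts flowering in this species. Apices were taken at 0, 3, 5 and 7 days after the move, with 2 arrays in each of the 20 groups of genotype and day. The genotypes were the accessions Columbia (Col) and Landsberg erecta (Ler) and the mutants lfy-12, co-2 and ft-2. LFY (LEAFY) is a transcription factor that gives young primordia a floral fate, CO (CONSTANS) links day length to flowering in the leaf, and FT (FLOWERING LOCUS T) is the mobile signal that travels from leaf to apex. The backgrounds are known for these alleles rather than stated in the labels: lfy-12 is a Columbia allele, and co-2 and ft-2 are Landsberg erecta alleles. The comparisons ask which transcripts of the apex change during the move to flowering and which of those changes depend on each gene. No arrays from plants kept in short days after day 0 were used here, so day length, age and sampling day changed together. The hour of sampling is not among the sample details used here, and no gene of the circadian clock list was measured. A shift in daily timing could therefore not be checked, for GI or other genes. LFY, CO, FT, AP1, SOC1, FUL and FLC have no probe set listed in the annotation used here, so their transcripts are not reported and the mutated genes could not be checked. Array medians lay between 6.91 and 7.07 on the log2 scale, and replicate arrays correlated at 0.990 to 0.997 across probe sets, where probe sets are not independent replicates. The SD of the difference between replicate arrays was 0.16 to 0.31 log2 units, with the highest value at Ler day 0. On 3 of the 40 arrays, transcripts that separate the backgrounds appeared at a median share of 9.41% (lfy-12 day 5 replicate 2), 5.85% (co-2 day 3 replicate 1) and 4.32% (ft-2 day 0 replicate 1) of their level in the other background. The other 37 arrays lay between -0.996% and 0.943%. Nothing in the labels says that replicates came from separate plants, so p-values measure only the spread between these samples, and the number of arrays limits the precision.

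In Col, AT5G44630, which encodes a sesquiterpene synthase, rose by 1.88 ± 0.19 log2 units by day 3, 3.14 ± 0.19 by day 5 and 4.67 ± 0.19 by day 7 (25.4-fold; SE, n = 2 arrays per day). WSD1, a wax ester synthase, rose 15.2-fold by day 7 (log2 3.92 ± 0.21), and AT3G28500, of the acidic ribosomal protein P2 family, rose 10.5-fold (3.40 ± 0.13). BAT1, an acyltransferase linked to brassinosteroid metabolism, rose 5.91-fold (2.56 ± 0.17). BCAT4, an aminotransferase of methionine-derived glucosinolate synthesis, fell by 5.63 ± 0.32 (49.5-fold), the largest fall among the named genes. AT2G25450, a dioxygenase that modifies glucosinolate side chains, fell by 3.09 ± 0.25, and PYK10, a beta-glucosidase of endoplasmic reticulum bodies, fell by 3.26 ± 0.23 (9.56-fold). Both had already fallen at day 3, by 1.73 ± 0.25 and 1.45 ± 0.23. AT1G56300 fell by 3.05 ± 0.35 at day 3, 4.13 ± 0.35 at day 5 and 4.03 ± 0.35 at day 7. The methionine sulfoxide reductase gene MSRB5 fell by 2.28 ± 0.24 at day 3. At day 3, 257 probe sets were called higher and 353 lower. At day 5 the counts were 1012 and 1363, and at day 7 they were 1627 and 1384, of which 252 rose and 381 fell by more than 2-fold. Of the 3011 probe sets called at day 7, 1483 have no gene listed and are counted here without a name. Leaving out any 1 of the 4 arrays lowered the count to between 208 and 355 at day 3 and to between 1192 and 1377 at day 5, and at day 7 the count was 1976 without Col day 7 replicate 2.

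**Figure D1:**
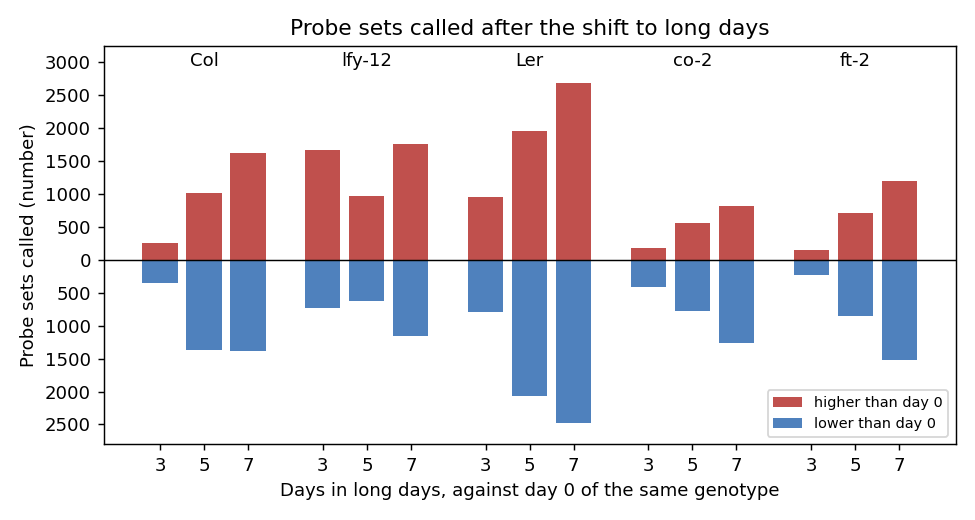
Number of probe sets called higher (upward bars) and lower (downward bars) against day 0, by genotype and day after the move to long days, at a Benjamini-Hochberg adjusted p under 0.05 with 2 arrays per group. At day 7, Ler had 2689 higher and 2473 lower probe sets, against 819 and 1255 in co-2 and 1194 and 1513 in ft-2.

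In Ler, AT5G44630 rose by 2.67 ± 0.19 at day 3, 4.41 ± 0.19 at day 5 and 5.05 ± 0.19 at day 7 (33.1-fold; SE, n = 2 arrays per day). WSD1 rose 26.8-fold by day 7 (log2 4.75 ± 0.21), AT5G22430 22.3-fold (4.48 ± 0.16), AT3G28500 11.9-fold (3.57 ± 0.13) and BAT1 7.34-fold (2.88 ± 0.17). BCAT4 fell by 4.94 ± 0.32 (30.7-fold), and BGLU33, of the beta-glucosidase family, fell by 4.25 ± 0.47 (19.0-fold). AOP3, a dioxygenase of glucosinolate modification, fell by 2.77 ± 0.28 at day 5. At day 3, the cold-induced gene COR15A had fallen by 1.83 ± 0.24 and MSRB5 by 1.93 ± 0.24. At day 3, 961 probe sets were called higher and 797 lower. These counts were 1964 and 2065 at day 5, and 2689 and 2473 at day 7, with 309 rises and 746 falls above 2-fold. The Ler day 0 arrays differed most from each other, and the total fell from 1758 to 1013 at day 3, from 4029 to 2330 at day 5 and from 5162 to 3355 at day 7 without Ler day 0 replicate 1. The day 3 total was also 672 without Ler day 3 replicate 1 and 1031 without Ler day 3 replicate 2, and 733 when only Ler arrays were fitted. The day 5 total was 2589 without Ler day 5 replicate 1 and 2387 from Ler arrays alone. From only the 4 arrays of Ler days 0 and 3, 43 probe sets were called with the replicate numbers crossed between the days as a block. With the same numbers joined, 127 were called.

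Most of the Col day 7 response was also called in Ler, on separate arrays. Most of the larger Ler response was not called in the same direction in Col, but most of its changes above 2-fold were. Of the 309 probe sets that rose more than 2-fold in Ler, 98.7% rose in Col and 286 were called higher there. Of the 746 that fell more than 2-fold, 97.7% fell in Col and 553 were called lower. A test of the difference in response itself called 398 probe sets between the accessions. Of the 1627 probe sets called higher in Col, 1184 were called higher in Ler (of 2689 there), where 192.3 were expected if the calls were independent, and 4 were called lower. Of the 1384 called lower in Col, 1081 were called lower in Ler (of 2473 there), against 150.5 expected, and 3 were called higher. The 252 probe sets that rose more than 2-fold in Col and the 381 that fell more than 2-fold were then followed in the other genotypes as a pair of sets. These sets were chosen after the Col values were seen and are measured elsewhere on separate arrays. The Col risers had a mean rise at day 7 of 1.58 log2 units in Col itself, 1.63 ± 0.06 in Ler, 1.19 ± 0.03 in lfy-12, 0.49 ± 0.08 in co-2 and 0.48 ± 0.01 in ft-2 (SD, n = 2 arrays). Of these 252, 237 were called higher in Ler, 217 in lfy-12, 105 in co-2 and 105 in ft-2. The Col fallers had a mean change of -1.98 ± 0.05 in Ler, -1.09 ± 0.06 in lfy-12, -1.06 ± 0.04 in co-2 and -0.71 ± 0.09 in ft-2. Each of these SDs, for risers and fallers, is that of the 2 day 7 arrays alone and leaves out the spread at day 0. For the Col fallers the day 0 arrays had SDs of 0.03 in Ler, 0.30 in lfy-12, 0.16 in co-2 and 0.10 in ft-2.

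**Figure D2:**
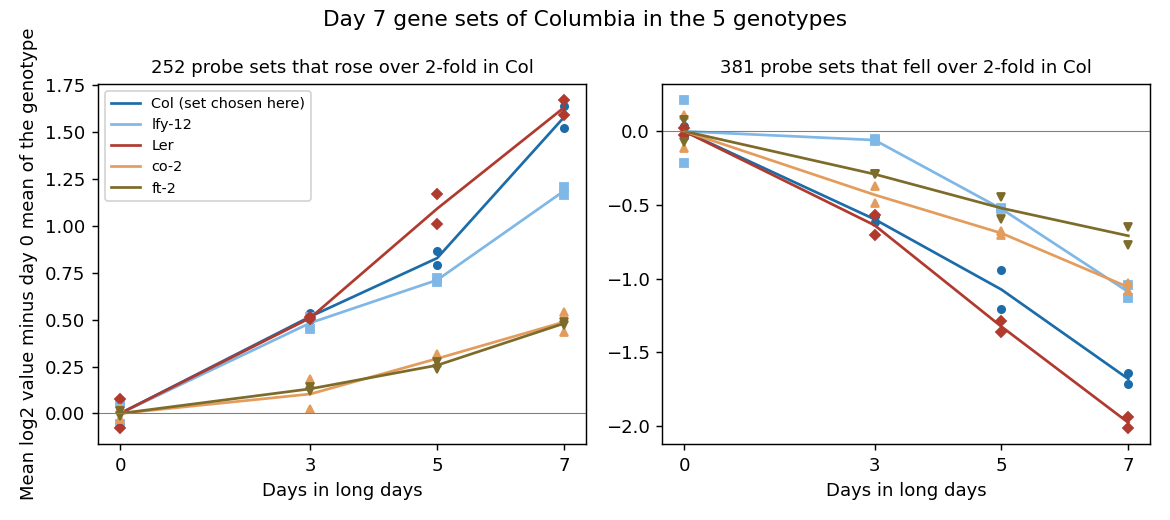
Mean log2 value of the 252 probe sets that rose and the 381 that fell more than 2-fold in Col by day 7, minus the mean of the same genotype at day 0, against days after the move to long days; points are single arrays and lines join group means for 5 genotypes. At day 7 the risers stood at 1.63 in Ler and 1.19 in lfy-12 but at 0.49 in co-2 and 0.48 in ft-2, and the Col lines belong to the arrays on which the sets were chosen.

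The fixed lists of flowering and apex genes held 221 genes, of which 21 could be measured by a probe set of their own. UFO, an F-box protein that works with LFY in floral meristems, rose by 1.46 ± 0.17 in Col and 1.89 ± 0.17 in Ler at day 7 (log2, SE, n = 2 arrays per day). FD, the bZIP partner of FT at the apex, rose by 0.89 ± 0.14 and 1.22 ± 0.14. The MADS-box gene AGL42 rose by 1.69 ± 0.18 and 2.06 ± 0.18, and SPL16, of the SQUAMOSA promoter-binding family, rose by 0.86 ± 0.10 in both. SMZ, an AP2-like repressor of flowering, fell by 1.17 ± 0.19 in Col and by 1.31 ± 0.19 in Ler. SNZ, another AP2-like repressor, was called lower in Ler but not in Col. In Ler it went from 6.07 ± 0.60 at day 0 to 5.26 ± 0.06 at day 7 (SD, n = 2 arrays). GI, a component of the photoperiod pathway, fell by 1.16 ± 0.14 in Col and by 0.70 ± 0.14 in Ler, where the value was -0.45 without Ler day 0 replicate 2. Of the 3 measured members of the floral meristem identity list, 2 rose in Col and 3 in Ler, with PUCHI, an AP2-family regulator of primordia, at 0.23 in Col and 0.61 in Ler. The Ler call for PUCHI was lost without Ler day 0 replicate 1 (0.57, adjusted p = 0.0575) or Ler day 7 replicate 2 (0.54, adjusted p = 0.0760). The list differed from other genes by camera with a preset correlation of 0.01 (adjusted p = 0.00507 in Col and 0.00261 in Ler), but adjusted p = 0.178 and adjusted p = 0.101 with an estimated correlation. The photoperiod pathway and floral repressor lists, with 3 measured members each, gave adjusted p = 0.876 and 0.295 in Col and 0.947 and 0.109 in Ler by the same preset test. The photoperiod list had a mean of 0.36 but a median of -0.27 in Ler. The median is that of AGL24, a MADS-box gene, which was higher at days 3 and 5 in Ler (0.27 and 0.24, calls lost without either Ler day 0 array) and lower at day 7 (-0.27 ± 0.08, adjusted p = 0.0152). Its day 7 call was lost without any 1 of the 4 arrays (-0.29 to -0.25) and from Ler arrays alone (adjusted p = 0.0916), and in Col it stood at 0.09 and was not called. COR15A and COR47, cold-induced genes that form the measured part of the abiotic stress list, fell by 2.09 ± 0.24 and 1.32 ± 0.23 in Col and by 2.19 ± 0.24 and 2.78 ± 0.23 in Ler. COR15A ended at 4.92 in Col and 4.53 in Ler, near the lower quartile of those arrays (4.73 and 4.70), so the floor may limit the size of its fall. Of the 21 genes, 4 rose and 5 fell in Col at day 7, with 11 called when adjusted over the list alone. In Ler, 6 rose and 9 fell, with 16 called when adjusted over the list alone. The 2 measured markers of leaf tissue, LHCB4.1 and RCA, fell by 0.64 ± 0.10 and 0.94 ± 0.31 in Ler, and neither was called in Col. The RCA call was lost without Ler day 0 replicate 1 (-0.17) or Ler day 7 replicate 2 (-0.75) and from Ler arrays alone (adjusted p = 0.138). YUC4, of the organ initiation list, was called lower at day 7, from 7.65 to 6.97 in Col and from 7.58 to 7.17 in Ler. SPL/NZZ was called higher in Ler only, from 4.87 to 5.33. CLV3, a signal of the stem cell niche, YAB3, a gene of organ polarity, ATC, a floral repressor, and PDF1.2A, a defensin gene, were not called in either accession at day 7. PDF1.2A stood near the floor, at 4.93 in Col and 4.84 in Ler at day 7.

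**Figure D3:**
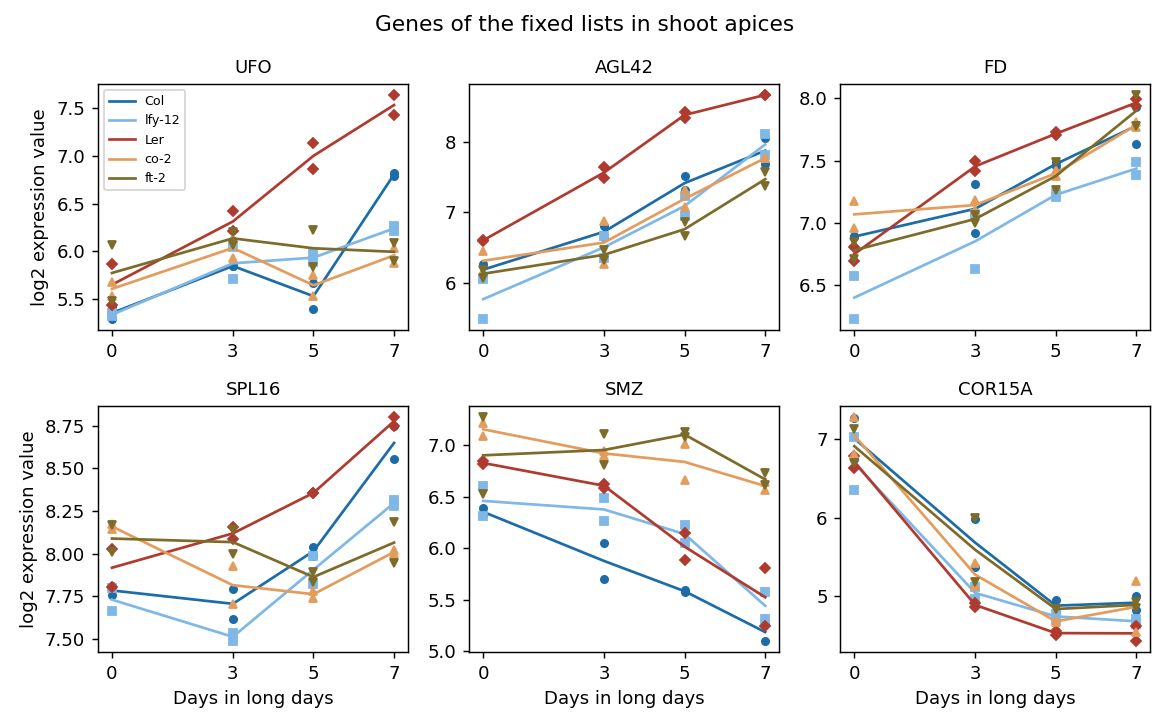
Log2 values of 6 genes from the fixed lists (UFO, AGL42, FD, SPL16, SMZ and COR15A) by days after the move to long days in 5 genotypes; points are single arrays and lines join group means. UFO and SPL16 rose in Col, Ler and lfy-12 but their changes at day 7 in co-2 were 0.35 and -0.15, which did not pass the test. COR15A fell in all 5 genotypes to day 7 means of 4.53 to 4.92, near the floor (array lower quartiles 4.66 to 4.92).

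In lfy-12, AT5G44630 rose by 4.39 ± 0.19 at day 7 (20.9-fold; SE, n = 2 arrays per day), AGL42 by 2.20 ± 0.18 (4.58-fold) and the thionin gene THI2.1 by 2.98 ± 0.47 (7.89-fold). BCAT4 fell by 3.89 ± 0.32 (14.9-fold), AT2G25450 by 3.09 ± 0.25 and PYK10 by 2.67 ± 0.23. At day 3, BGLU45, of the beta-glucosidase family, rose by 1.59 ± 0.14 and the transcription factor gene bZIP58 by 1.53 ± 0.16, while AT1G56300 fell by 3.98 ± 0.35. Among the list genes at day 7, UFO rose by 0.91 ± 0.17, FD by 1.04 ± 0.14 and SPL16 by 0.57 ± 0.10, SMZ fell by 1.02 ± 0.19 and GI by 1.19 ± 0.14. YUC4 was called lower, with means of 7.68 at day 0 and 7.20 at day 7. In all, 5 of the 21 list genes rose and 5 fell, with 11 called when adjusted over the list alone. The floral meristem identity list, with 2 of 3 members called higher, gave adjusted p = 0.00710 by camera and adjusted p = 0.172 with an estimated correlation. At day 3, 1662 probe sets were called higher and 726 lower, at day 5 967 and 622, and at day 7 1760 and 1155, and quantile normalization left 1374 higher and 981 lower at day 3. Without lfy-12 day 0 replicate 2 the totals fell from 2388 to 708 at day 3, from 1589 to 890 at day 5 and from 2915 to 1726 at day 7. They were 1032 and 1280 at day 3 without replicate 1 or 2 of that day, 871 and 707 at day 5 without replicate 1 or 2 of that day, and 1634 and 1644 at day 7 without replicate 1 or 2 of that day. The array with Landsberg erecta transcripts, lfy-12 day 5 replicate 2, is the one whose absence gave 707.

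The response from day 0 to day 7 was smaller in lfy-12 than in Col for AT5G22430 (log2 difference -1.62 ± 0.23, adjusted p = 0.000396), for the SPIRAL1-like gene SP1L2 (-1.50 ± 0.26, adjusted p = 0.00526) and for AT4G11190 (-1.23 ± 0.20, adjusted p = 0.00299). Each of these calls held in every alternative that was run. WSD1 had a difference of -1.62 ± 0.30 and AT3G45160 of 2.19 ± 0.44, the latter having fallen 17.2-fold in Col. The WSD1 call was lost without Col day 0 replicate 1 (-1.53), Col day 7 replicate 2 (-1.42), lfy-12 day 0 replicate 2 (-1.55) or lfy-12 day 7 replicate 2 (-1.51), and that of AT3G45160 without the same arrays (2.09, 2.24, 1.65 and 2.09) or Col day 7 replicate 1 (2.14). Both calls were also lost from the arrays of Col and lfy-12 alone (adjusted p = 0.0886 and 0.0600) and when counted from day 3 (-0.39 and 0.70). None of the 21 list genes was called by limma, and 1 was called when adjusted over the list alone. Larger shortfalls, above 8-fold, were called at 2 probe sets with no gene listed. Their differences were -4.55 ± 0.40 (adjusted p = 2.10e-07) and -3.16 ± 0.30 (adjusted p = 2.47e-07). The first went from 4.50 to 9.44 in Col and from 4.52 to 4.91 in lfy-12. These single values were not repeated under the alternatives. In all, 30 probe sets had a higher and 21 a lower response in lfy-12, out of 1292 with an unadjusted p under 0.05. The total of 51 became 21 without Col day 0 replicate 1, 18 without Col day 7 replicate 2, 217 without lfy-12 day 0 replicate 1, 16 without lfy-12 day 0 replicate 2 and 22 without lfy-12 day 7 replicate 2. It was 23 with a filter on low values, 33 from the arrays of Col and lfy-12 alone, and 22 (2 higher, 20 lower) when the response was counted from day 3. The 309 probe sets that rose more than 2-fold in Ler, chosen on other arrays, had a lower response in lfy-12 than in Col, with a mean difference of -0.34 (fry adjusted p = 0.000151). The 746 Ler fallers had a mean difference of 0.40 (fry adjusted p = 0.00509), which was 0.21 without lfy-12 day 0 replicate 2 (adjusted p = 0.0571) and 0.06 when counted from day 3 (adjusted p = 0.782).

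In co-2, AT5G44630 rose by 2.91 ± 0.19 at day 7 (7.52-fold; SE, n = 2 arrays per day), AT3G28500 by 2.57 ± 0.13 (5.93-fold) and AGL42 by 1.46 ± 0.18. BGLU33 fell by 3.07 ± 0.47 and AOP3 by 2.72 ± 0.28. The cold-induced genes COR15A and COR47 fell by 1.78 ± 0.24 and 1.39 ± 0.23 at day 3 and by 2.18 ± 0.24 and 2.16 ± 0.23 at day 7. FD rose by 0.72 ± 0.14 at day 7 and GI fell by 0.83 ± 0.14, whereas UFO, SPL16 and SMZ stood at 0.35, -0.15 and -0.55 and were not called, nor were LHCB4.1 and RCA (-0.01 and -0.12). The repressor SNZ was called lower, with means of 6.30 at day 0 and 5.32 at day 7. GID1A, a gibberellin receptor gene, was called higher, from 8.22 to 8.63. YUC4 stood at 7.61 at both days and was not called, but its response was not called different from Ler. Of the 21 list genes, 3 rose and 4 fell at day 7, with 8 called when adjusted over the list alone. The floral meristem identity list, with 1 of 3 members called, gave adjusted p = 0.202 by camera. At day 3, 180 probe sets were called higher and 415 lower, at day 5 564 and 772, and at day 7 819 and 1255. The total at day 3 was 595, and it was 69 without co-2 day 0 replicate 2, 132 without co-2 day 3 replicate 1, the array with Columbia transcripts, 977 without co-2 day 3 replicate 2, and 304 from co-2 arrays alone. At day 5 the total of 1336 became 531, 757 and 540 without co-2 day 0 replicate 2, day 5 replicate 1 and day 5 replicate 2. At day 7 the total of 2074 became 924 without co-2 day 0 replicate 2 and 1074 without co-2 day 7 replicate 2.

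The day 7 response was smaller in co-2 than in Ler, with log2 differences of -4.36 ± 0.23 for AT5G22430 (adjusted p = 7.76e-13), -3.98 ± 0.30 for WSD1 (adjusted p = 3.26e-10), -2.77 ± 0.24 for BAT1 and -2.68 ± 0.19 for REM22, of the B3 domain family (n = 2 arrays in each of 4 groups). The difference was 2.69 ± 0.45 for BCAT4, which fell in Ler, and 2.00 ± 0.21 for DFR, an enzyme of anthocyanin synthesis. UFO differed by -1.54 and SPL16 by -1.01, the latter being -0.46 (adjusted p = 0.0625) when counted from day 3. AGL24, a MADS-box promoter of flowering that had fallen in Ler and stood at 0.14 in co-2, differed by 0.42, a call lost without any 1 of the arrays (0.30 to 0.44) except co-2 day 7 replicate 1, and LHCB4.1, a light-harvesting protein gene, by 0.62, a call lost without Ler day 0 replicate 1 (0.38, adjusted p = 0.0793) and when counted from day 3 (0.29). Both were also lost from the arrays of co-2 and Ler alone (adjusted p = 0.115 and 0.0526). Of the 21 list genes, 2 had a higher and 2 a lower response in co-2, with 7 called when adjusted over the list alone. The floral meristem identity list gave adjusted p = 0.0357 by camera and adjusted p = 0.302 with an estimated correlation. The 2 probe sets with no gene listed that fell short above 8-fold in lfy-12 differed by -5.62 ± 0.40 and -4.75 ± 0.30 here. In all, 585 probe sets had a higher and 642 a lower response in co-2. The total of 1227 became 1967 without Ler day 0 replicate 2 and 681 when counted from day 3. All values counted from day 3 here use co-2 day 3 replicate 1, the array with Columbia transcripts. The Col risers, chosen on other arrays, differed by a mean of -1.14 (fry adjusted p = 5.29e-11), and the Col fallers by 0.92 (fry adjusted p = 9.79e-07).

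**Figure D4:**
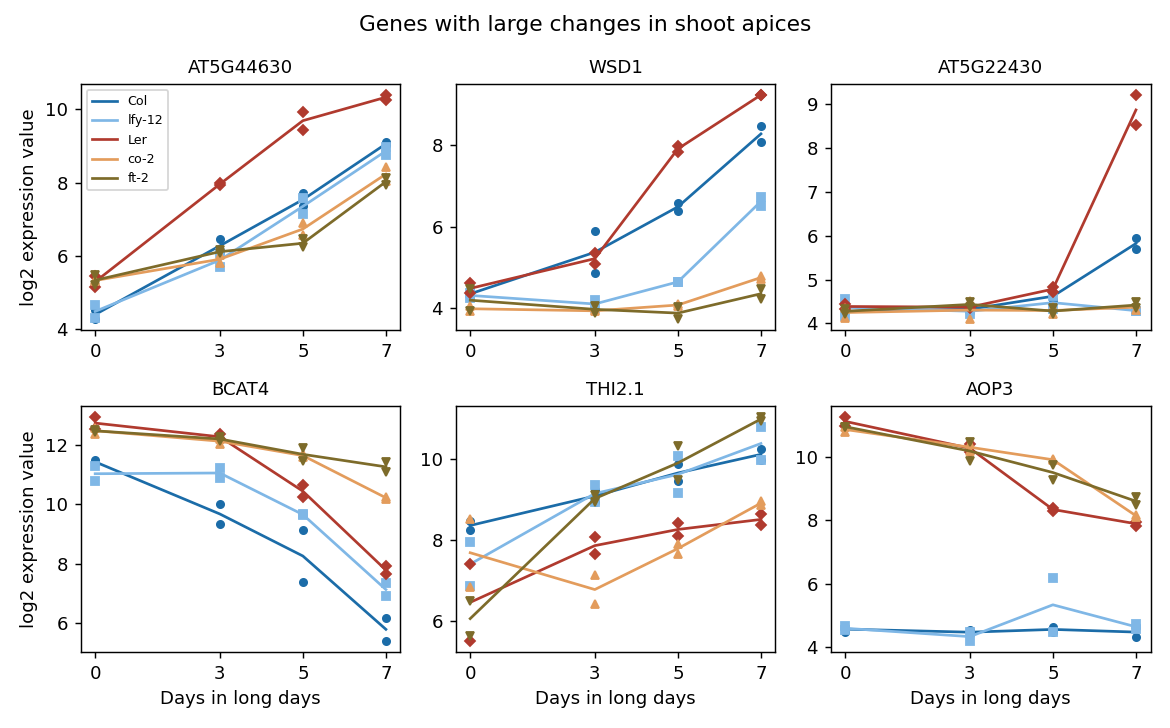
Log2 values of 6 genes named by the size of their change (AT5G44630, WSD1, AT5G22430, BCAT4, THI2.1 and AOP3) by days after the move to long days in 5 genotypes; points are single arrays and lines join group means. WSD1 rose 26.8-fold in Ler by day 7, with response differences from Ler of -3.98 log2 units in co-2 and -4.59 in ft-2, and THI2.1 rose 30.5-fold in ft-2.

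In ft-2, THI2.1 rose by 2.97 ± 0.47 at day 3, 3.85 ± 0.47 at day 5 and 4.93 ± 0.47 at day 7 (30.5-fold; SE, n = 2 arrays per day), the largest rise among its named genes. AT5G44630 rose by 2.69 ± 0.19 at day 7 (6.47-fold) and AT3G28500 by 2.37 ± 0.13 (5.18-fold), while AOP3 fell by 2.35 ± 0.28 and COR15A by 2.02 ± 0.24. FD rose by 1.12 ± 0.14 and AGL42 by 1.34 ± 0.18, GI fell by 0.75 ± 0.14, and UFO, SPL16 and SMZ stood at 0.22, -0.02 and -0.23 and were not called. The repressor SNZ was called lower, with means of 6.33 at day 0 and 5.45 at day 7. GID1A was called higher, from 8.15 to 8.57, as was PHV of the shoot meristem list, from 9.82 to 10.13. YUC4 went from 7.47 to 7.58 and was not called, but its response was not called different from Ler. LHCB4.1 and RCA fell by 0.43 ± 0.10 and 1.31 ± 0.31, calls lost without ft-2 day 0 replicate 2 (-0.38 and -1.15) or ft-2 day 7 replicate 2 (-0.39 and -1.18). Of the 21 list genes, 6 rose and 6 fell at day 7, with 13 called when adjusted over the list alone. The floral meristem identity list, with 2 of 3 members called higher, gave adjusted p = 0.0202 by camera and adjusted p = 0.307 with an estimated correlation. By camera at day 7, the photoperiod list gave adjusted p = 0.491, 0.977 and 0.677 in lfy-12, co-2 and ft-2, and the floral repressor list 0.181, 0.381 and 0.508. At day 3, 150 probe sets were called higher and 236 lower, at day 5 707 and 850, and at day 7 1194 and 1513. The total at day 3 was 386, and it was 97 without ft-2 day 0 replicate 2 and 47 without ft-2 day 3 replicate 2, and 2156 with the replicate numbers crossed between the days as a block, against 51 with the same numbers joined. At day 5 the total of 1557 became 676, 342 and 903 without ft-2 day 0 replicate 2, day 5 replicate 1 and day 5 replicate 2. At day 7 the total of 2707 became 1182, 1452 and 1138 without ft-2 day 0 replicate 2, day 7 replicate 1 and day 7 replicate 2. The array with Columbia transcripts, ft-2 day 0 replicate 1, enters every one of these comparisons, and without it the totals were 553, 1427 and 2456.

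The day 7 response was also smaller in ft-2 than in Ler, with log2 differences of -4.59 ± 0.30 for WSD1 (adjusted p = 1.74e-11), -4.34 ± 0.23 for AT5G22430 (adjusted p = 8.74e-13), -2.90 ± 0.24 for BAT1 and -2.70 ± 0.19 for REM22 (n = 2 arrays in each of 4 groups). Positive differences were 3.73 ± 0.45 for BCAT4 and 2.76 ± 0.21 for DFR. THI2.1 differed by 2.88 ± 0.67, a call lost without Ler day 0 replicate 1 (1.93, adjusted p = 0.0608) and when counted from day 3 (1.32). UFO differed by -1.67, SPL16 by -0.88 and AGL24 by 0.55 (0.28 in ft-2). SMZ differed by 1.07, a call lost without Ler day 7 replicate 1 (0.79, adjusted p = 0.109), without ft-2 day 0 replicate 1, the array with Columbia transcripts (0.70, adjusted p = 0.123), and when counted from day 3 (0.80) or from the arrays of ft-2 and Ler alone (adjusted p = 0.0544). Of the 21 list genes, 3 had a higher and 2 a lower response in ft-2, with 9 called when adjusted over the list alone, and the floral meristem identity list gave adjusted p = 0.240 by camera. The 2 probe sets with no gene listed that fell short above 8-fold in lfy-12 differed by -5.51 ± 0.40 and -5.04 ± 0.30 here. In all, 893 probe sets had a higher and 738 a lower response in ft-2, and the total of 1631 became 945 when counted from day 3. The Col risers differed by a mean of -1.15 (fry adjusted p = 5.11e-11) and the Col fallers by 1.27 (fry adjusted p = 7.47e-09). The same Ler arrays enter the comparisons of co-2 and of ft-2, so the 2 results are not independent.

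Between ft-2 and co-2, the response of 1 probe set, for which no gene is listed, was called (1.51 ± 0.25 higher in ft-2), and none of the 21 list genes was called, with 2 called when adjusted over the list alone. The unadjusted p was under 0.05 for 1827 probe sets. The count of 1 was 0 without co-2 day 7 replicate 1 or ft-2 day 7 replicate 1, 2 without co-2 day 7 replicate 2 or ft-2 day 7 replicate 2, 15 without ft-2 day 0 replicate 1, the array with Columbia transcripts, and 3 without ft-2 day 0 replicate 2. It was 0 with a replicate block, without the intensity trend or counted from day 3, and 98 from the arrays of both mutants alone. The Col risers differed by a mean of -0.01 (fry adjusted p = 0.827). The Col fallers fell less in ft-2, by a mean of 0.35 (fry adjusted p = 0.0148), a call lost without co-2 day 0 replicate 2 (0.24), ft-2 day 0 replicate 1 (0.27) or ft-2 day 7 replicate 1 (0.29) and when counted from day 3 (0.21). On separate arrays, co-2 and ft-2 shared 486 probe sets called higher at day 7, against 43.0 expected from independent calls, and 583 called lower, against 83.5 expected.

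Ler had a larger day 7 response than Col for AT5G22430 (log2 difference 2.94 ± 0.23, adjusted p = 6.21e-09), REM22 (1.98 ± 0.19) and RXF26 (2.42 ± 0.29). The response of AOP3 differed by -3.13 ± 0.39 (adjusted p = 2.25e-05), and that of AT5G58390 by -2.70 ± 0.23. AOP3 stood at 4.57 and 4.47 in Col at days 0 and 7, below the lower quartile of those arrays (4.78 and 4.73), so it had little room to fall there. COR47 differed by -1.46, a call lost without Col day 0 replicate 2 or Ler day 7 replicate 2 (-1.41 in both, adjusted p = 0.0530 and 0.0550) and when counted from day 3 (-0.44). It was the only 1 of the 21 list genes called, and 6 were called when adjusted over the list alone. No list was called by camera in the response differences of lfy-12 and Col, ft-2 and co-2 or Ler and Col, nor between the accessions at day 0. Probe sets with a higher response in Ler numbered 125, and 273 had a lower response. The total of 398 became 247 without Col day 0 replicate 2, 228 without Col day 7 replicate 1, 986 without Ler day 0 replicate 2, 244 and 250 without Ler day 7 replicate 1 and 2, and 235 when counted from day 3.

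At day 0, before the move to long days, HEMA2, a glutamyl-tRNA reductase of tetrapyrrole synthesis, was lower in lfy-12 than in Col (log2 difference -1.52 ± 0.13, adjusted p = 4.09e-08, n = 2 arrays per group), as was AT3G11000 (-1.56 ± 0.20), while AT3G05170 was higher by 1.96 ± 0.17. AT2G28570 was higher in each mutant than in its wild type, by 1.05 ± 0.14 in lfy-12, 1.81 ± 0.14 in co-2 and 1.74 ± 0.14 in ft-2. AT1G35612 was lower in co-2 than in Ler (-1.98 ± 0.23), and the calls for both it (-1.16 ± 0.23) and AT5G32460 (-1.31 ± 0.16) in ft-2 were lost with crossed replicate numbers as a block. None of the 21 list genes was called in any of the 3 mutants, and 2, 5 and 2 were called in lfy-12, co-2 and ft-2 when adjusted over the list alone. In lfy-12, 70 probe sets were called higher and 376 lower. In co-2 the counts were 669 and 175, and in ft-2 482 and 167, and with quantile normalization they were 284 and 258 in co-2 and 252 and 266 in ft-2. The lfy-12 total of 446 became 144 and 269 without Col day 0 replicate 1 and 2, and 670 and 244 without lfy-12 day 0 replicate 1 and 2. The co-2 total of 844 became 149 and 1921 without Ler day 0 replicate 1 and 2, 240 and 430 without co-2 day 0 replicate 1 and 2, 484 with a filter on low values, 184 from the arrays of co-2 and Ler alone and 1933 with the lower quartile of each array as a covariate. From the 4 day 0 arrays of co-2 and Ler with replicate numbers as a block, limma called 0 probe sets with the numbers joined and 0 with them crossed. An unadjusted p under 0.05 was found for 2514 and 2756, and each co-2 call named here was lost in these fits. Such fits of 4 arrays, also used for ft-2, have far fewer residual degrees of freedom than the 20 of the main model. Calls lost in them do not decide whether the numbers pair the arrays. The ft-2 total of 649 became 1005 without Ler day 0 replicate 1, 247 without ft-2 day 0 replicate 1, the array with Columbia transcripts, 338 with the filter, 335 from the arrays of ft-2 and Ler alone, 1198 with the covariate and 4 with crossed replicate numbers as a block, against 0 by limma with the same numbers joined (1955 with an unadjusted p under 0.05).

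Between the accessions at day 0, AOP3 was higher in Ler by 6.54 ± 0.28 log2 units (93.0-fold, adjusted p = 2.55e-16, n = 2 arrays per group), AT4G19240 by 4.78 ± 0.31 and AT5G15360 by 4.26 ± 0.25. With AOP3 near the floor in Col, its fold depends on the background level. AT2G01090 was 37.5-fold lower in Ler (-5.23 ± 0.31), AT3G43740 32.4-fold (-5.02 ± 0.23) and AT5G45500 32.3-fold (-5.02 ± 0.29). Of the 21 list genes, SNZ, an AP2-like repressor of flowering, was higher in Ler by 0.73 and COR47 was 2.29-fold higher, GID1A, a gibberellin receptor gene, differed by -0.52, and 5 were called when adjusted over the list alone. The SNZ call was lost without Col day 0 replicate 2 (0.63, adjusted p = 0.0738) or Ler day 0 replicate 1 (0.30, adjusted p = 0.340), and its difference was 1.15 without Ler day 0 replicate 2. In all, 1955 probe sets were called higher in Ler and 3056 lower. Above 8-fold, 10 were higher and 37 lower. The array was built on the Columbia sequence, and both the level of a transcript and the match of its probes enter these values.

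Gene families were grouped by the stem of the symbol after the data were seen, and 41 sets were tested per comparison. In the IQD family of calmodulin-binding proteins, 7 of 15 genes rose in Col at day 7 (camera adjusted p = 0.00101, adjusted p = 0.367 with an estimated correlation), 8 rose and 1 fell in Ler (0.00586, adjusted p = 0.301 with an estimated correlation) and 3 rose in lfy-12 (0.0326, adjusted p = 0.557 with an estimated correlation). Of 69 genes of the plastid genome, 7 fell in Col, 26 in Ler, 5 in lfy-12 and 4 in ft-2, with mean changes of -0.39, -0.45, -0.35 and -0.23, and none of these set calls held with an estimated correlation (adjusted p = 0.741, 0.592, 0.642 and 0.900). The response of these plastid genes was higher in co-2 than in Ler by a mean of 0.59, with 6 called (camera adjusted p = 9.67e-17, adjusted p = 0.302 with an estimated correlation). Among 14 BZIP genes the response was lower in Ler than in Col, with a mean difference of -0.38 and 2 called, and this call held with an estimated correlation (camera adjusted p = 0.00894 and adjusted p = 0.0339 with an estimated correlation). No mean of these families changed sign with quantile normalization.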

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

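The tests of the Ler day 0 arrays, of RNA quality and of CO or FT activity on the Ler response, and those of falls above 8-fold, of the direction and the excess of falls on other arrays and of probe match, were chosen after the result was seen. The bounds of the other tests here were fixed before their results, although the array floor covariate that some of them use was chosen after the data were seen.

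The counts and genes in this paragraph and the next were singled out because the response from day 0 to day 7 differed between genotypes by a test of the difference itself. The response differed at 51 probe sets between lfy-12 and Col, 1227 between co-2 and Ler, 1631 between ft-2 and Ler, 1 between ft-2 and co-2 and 398 between Ler and Col. The arrays on which these counts depend, and the counts without them, were 16 (without lfy-12 day 0 replicate 2), 18 (Col day 7 replicate 2), 21 (Col day 0 replicate 1), 22 (lfy-12 day 7 replicate 2) and 217 (lfy-12 day 0 replicate 1) for lfy-12 against Col, and 1967 (Ler day 0 replicate 2) for co-2 against Ler. For ft-2 against co-2 they were 0 (co-2 or ft-2 day 7 replicate 1), 2 (co-2 or ft-2 day 7 replicate 2), 3 (ft-2 day 0 replicate 2) and 15 (ft-2 day 0 replicate 1). For Ler against Col they were 228 (Col day 7 replicate 1), 244 and 250 (Ler day 7 replicate 1 and 2), 247 (Col day 0 replicate 2) and 986 (Ler day 0 replicate 2).

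Between lfy-12 and Col, the response differed by 2.19 log2 units at AT3G45160, 1.84 at AT5G05250, -1.62 at AT5G22430 and -1.62 at WSD1. Of these, AT5G22430 was called without each array in turn, and the other 3 calls were lost without Col day 0 replicate 1 (2.09, 1.56 and -1.53), Col day 7 replicate 2 (2.24, 1.65 and -1.42), lfy-12 day 0 replicate 2 (1.65, 1.57 and -1.55) or lfy-12 day 7 replicate 2 (2.09, 1.73 and -1.51), and AT3G45160 also without Col day 7 replicate 1 (2.14). Between co-2 and Ler, it differed by 2.70 at AT3G45160, 2.69 at BCAT4, -4.36 at AT5G22430, -3.98 at WSD1, -1.54 at UFO, -1.01 at SPL16, 0.42 at AGL24 and 0.62 at LHCB4.1. The AGL24 call was lost without any 1 of the arrays (0.30 to 0.44) except co-2 day 7 replicate 1, and that of LHCB4.1 without Ler day 0 replicate 1 (0.38). Between ft-2 and Ler, it differed by 3.73 at BCAT4, 3.72 at AT3G45160, -4.59 at WSD1, -4.34 at AT5G22430, -1.67 at UFO, -0.88 at SPL16, 0.55 at AGL24, 1.07 at SMZ and 1.04 at COR47. The SMZ call was lost without Ler day 7 replicate 1 (0.79) or ft-2 day 0 replicate 1 (0.70), and the COR47 call without any 1 of the arrays (0.75 to 1.09) except Ler day 0 replicate 1 and ft-2 day 0 replicate 2. Between Ler and Col, it differed by 2.94 at AT5G22430, 2.56 at AT3G53980, -3.13 at AOP3 (near the floor in Col), -2.70 at AT5G58390 and -1.46 at COR47, whose call was lost without Col day 0 replicate 2 or Ler day 7 replicate 2 (-1.41 in both).

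The response at day 7 was larger in Ler than in co-2 and ft-2, as in WSD1 and UFO. The Ler day 0 arrays, which differed from each other more than any other replicates, were argued against as the whole cause. The Col risers still differed by -0.74 between co-2 and Ler (fry adjusted p = 2.05e-07) and by -0.77 between ft-2 and Ler (fry adjusted p = 1.14e-07) when counted from day 3 to day 7. For co-2 this baseline includes day 3 replicate 1, the array with Columbia transcripts. The risers stood at 0.03 on it, against 0.18 on replicate 2, and the test was not repeated without it. With the lower quartile of each array as a covariate, 1389 probe sets were called for co-2 and 1818 for ft-2. This quartile changed little, from 4.72 at day 0 to 4.70 at day 7 in Ler, 4.77 to 4.81 in co-2 and 4.77 to 4.82 in ft-2. The covariate could therefore move these differences little, so the counts do not decide on a shift in the array floor. RNA quality cannot be told apart from an effect of the mutations: the ubiquitin 3' to 5' contrast was 0.84 to 0.91 in the Ler groups, 0.60 to 0.66 in co-2 and 0.60 to 0.80 in ft-2, but it changed little from day 0 to day 7 (0.91 and 0.90 in Ler, 0.65 and 0.60 in co-2, 0.72 and 0.65 in ft-2), so as a covariate (1328 and 1669 calls) it moved the differences of co-2 and Ler by a median of 0.01 log2 units and was no test of this, while the actin contrast went from 0.91 to 0.96 in Ler, 0.80 to 0.66 in co-2 and 1.17 ± 0.59 to 0.71 ± 0.07 in ft-2 (SD, n = 2 arrays) and that of GAPDH from 0.02 to 0.04, -0.11 to -0.14 and 0.01 to -0.15, and neither was tried as a covariate. Loss of CO or FT activity may account for the pattern, but it could not be separated from other differences between whole genotypes. Over both mutants and both wild types, each with risers chosen in the other accession, the weakest of 4 differences was -0.78 (fry adjusted p = 2.97e-10). Those from Ler were the differences of the Col risers already given. The 4 differences share arrays, since each wild type was set against both mutants, so they are not independent. Other differences between genotypes could give the same values, so they do not single out CO or FT. Differences in the growth or processing of whole genotypes, in the backgrounds of the mutant lines and in the share of leaf tissue, whose 2 measured markers fell in Ler and ft-2 but were not called in co-2, stay open, and none was tested as a cause.

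More probe sets were called in lfy-12 at day 3 (2388) than at day 5 (1589), and most of the day 3 calls were rises. Without lfy-12 day 0 replicate 2 the ratio of day 3 to day 5 calls was 0.796 (708 against 890), so this array is a candidate source of the excess. With the array floor as a covariate, day 3 still had more calls than day 5 (1935 against 1617) and 66.5% of them were rises, but an effect of the floor on the direction cannot be told apart from a change in the plants, because this share passed the bound set in advance by less than 2 binomial standard errors (1.07 each) and fell to 58.3% with quantile normalization. The array with Landsberg erecta transcripts, lfy-12 day 5 replicate 2, also enters the day 5 count, which was 707 without it. An early rise of transcripts in lfy-12 stays open.

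At day 0, large falls outnumbered large rises in Ler against Col, with 37 against 10 above 8-fold and 432 against 328 above 2-fold. For falls above 8-fold, an origin in the Ler day 0 arrays was argued against, because 94.6% (35 of 37) were more than 2-fold lower in co-2 and ft-2 than in lfy-12 at day 7, on other arrays. Of the falls above 2-fold, 95.6% (413 of 432) were lower there, against 38.8% of all probe sets, which argued against these arrays as the only origin of their direction, but 51.4% were more than 2-fold lower, between the bounds set in advance, so an addition by these arrays to the size of the falls cannot be told apart from a difference between the accessions. The excess of falls above 2-fold could come from these arrays, since at day 0, without any Ler array, 246 probe sets were more than 2-fold lower and 354 higher in co-2 and ft-2 than in lfy-12 (ratio 0.695), although effects of the mutations and the array with Columbia transcripts enter this test. Probes made on the Columbia sequence could contribute, since the odds of a fall against a rise were higher above 8-fold than between 2-fold and 8-fold (odds ratio 2.97, Fisher's exact p = 0.00205), and lower expression or absence of these genes in Ler would give the same values and stays open.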

How the results depend on the processing

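The array floor and ubiquitin contrast covariates, the response counted from day 3, the crossed replicate numbers and the alternatives for the sets and for the differences held at all days were chosen after the data were seen, and the others before. Of 274 counts under other settings, over 25 results, 184 stayed within 1.5 times the reported count. Of 6085 values of named genes, 5554 kept their call, 528 were no longer called and 3 turned in sign. These genes were named for large, non-overlapping changes or as called list members on the same arrays. Their share of kept calls therefore does not describe the calls in general. Pseudocounts were not run, since the values were already log2. Signal over background limits the transcripts near the floor, where the lower quartile of the arrays was 4.66 to 4.92 and the bacterial controls 3.60 to 3.78. The differences of the Col risers between co-2 or ft-2 and Ler were called in every setting run for them, from -1.23 to -1.07 without any 1 array. Family tests were repeated with an estimated correlation and their means with quantile normalization.

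For each setting below the cause was not tested, except that the filter tests fewer probe sets and that leaving out arrays, or fitting only the genotypes compared, leaves fewer arrays. Quantile normalization gave 542 for co-2 against Ler at day 0. The filter on low values gave 23 for the response difference of lfy-12 and Col, and 484 and 338 for co-2 and ft-2 against Ler at day 0. For the response difference of ft-2 and co-2, fits without the intensity trend and with a replicate block gave 0 each. The replicate block left the other 24 results within 1.5 times. Whether replicate numbers pair the arrays stays open: over 190 pairs of groups, the deviations of replicate 1 correlated from -0.50 to 0.40 across probe sets, with 52 pairs over 0.1 and 35 under -0.1. With crossed numbers as a block in the 4 arrays of a comparison, the counts were 43 for Ler at day 3, 2156 for ft-2 at day 3 and 4 for ft-2 against Ler at day 0. With the same numbers joined they were 127, 51 and 0. Fits of 4 arrays have far fewer residual degrees of freedom than the 20 of the main model, so these counts do not decide on pairing. Over 19 comparisons, the joined numbers gave more calls in 10, the crossed ones in 8, and co-2 against Ler at day 0 had 0 by limma either way (2514 and 2756 with an unadjusted p under 0.05). Joined against crossed, the counts were 3131 and 1050 for Ler against Col at day 0, 405 and 193 for lfy-12 against Col at day 0 and 1914 and 399 for ft-2 at day 5, but 352 and 813 for Col at day 3 and 1492 and 2158 for co-2 at day 5. Only the arrays of the genotypes compared gave 733 and 2387 for Ler at days 3 and 5, 304 for co-2 at day 3, 33 and 98 for the response differences of lfy-12 and Col and of ft-2 and co-2, and 184 and 335 for co-2 and ft-2 against Ler at day 0. The array floor covariate gave 1933 and 1198 for the latter pair. Counted from day 3, the response differences were 22 for lfy-12 and Col, 681 for co-2 and Ler, 945 for ft-2 and Ler, 0 for ft-2 and co-2 and 235 for Ler and Col, and 3 differences between lfy-12 and Col turned, to -0.28 at AT1G19540, -0.0817 at BGLU45 and -0.0237 at AT3G22750.

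Without each array in turn, the lowest and highest counts for days 3, 5 and 7 were 208 to 355, 1192 to 1377 and 1976 to 2264 in Col, 672 to 2187, 2330 to 4063 and 3355 to 5145 in Ler, 708 to 2742, 707 to 1415 and 1634 to 2861 in lfy-12, 69 to 977, 531 to 1019 and 924 to 1868 in co-2, and 47 to 553, 342 to 1427 and 1138 to 2456 in ft-2. Response differences ran from 16 to 217 for lfy-12 and Col, 839 to 1967 for co-2 and Ler, 1137 to 1705 for ft-2 and Ler, 0 to 15 for ft-2 and co-2 and 228 to 986 for Ler and Col. At day 0 the counts ran from 144 to 670 for lfy-12 against Col, 149 to 1921 for co-2 and 247 to 1005 for ft-2 against Ler, and 3354 to 4881 for Ler against Col.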

Other observations

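All tests in this part, and the genes named in it, were chosen after the data were seen. Some differences between mutant and wild type were present on every sampling day. At all 4 days, 9 probe sets were called higher and 120 lower in lfy-12 than in Col, 105 higher and 25 lower in co-2 than in Ler, and 125 higher and 36 lower in ft-2 than in Ler. With quantile normalization these were 8 and 114 in lfy-12, 56 and 47 in co-2 and 73 and 68 in ft-2, so the excess of higher over lower in co-2 and ft-2 depended on the normalization, and the array means lay at 6.83 to 6.86 in Ler, 6.89 to 6.91 in co-2 and 6.90 to 6.91 in ft-2. Without any 1 array the totals ran from 83 to 113 in lfy-12, 53 to 133 in co-2 and 82 to 148 in ft-2. HEMA2 was lower in lfy-12 than in Col by a mean of -1.35 log2 units over the 4 days (from -1.52 to -1.17), and AT3G11000 by -1.71 (from -1.92 to -1.50). AT2G28570 was higher in co-2 than in Ler by a mean of 1.94, with a lowest value of 1.81. Its day 0 call was lost when only the 4 day 0 arrays of co-2 and Ler were fitted with replicate numbers as a block. That fit gave 0 calls by limma, but it has far fewer residual degrees of freedom than the 20 of the main model. The loss therefore does not decide on pairing. With a replicate block on all 40 arrays, 570 of 572 values of named genes kept their call. Of the probe sets held at all days, 8 were held in each of the 3 mutants, 6 of them in 1 direction: AT2G28570 and AT1G21550 were higher in each mutant, and AT4G00870 and AT2G32340 lower. AT5G47050 was lower in lfy-12 and higher in co-2 and ft-2. Since co-2 and ft-2 were compared with the same Ler arrays, their agreement may come in part from these. No count expected by chance was computed for the 3 mutants together. Between lfy-12 and co-2, which were compared with separate wild types, 3 held rises were shared, against 0.0415 expected from independent calls, and 3 held falls, against 0.132. As many, 3 against 0.554 expected, were lower in lfy-12 and higher in co-2, so the overlap was not confined to 1 direction.

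The wild types kept changing after day 3, whereas fewer probe sets were called between days 3 and 7 in the late-flowering mutants. Day 7 differed from day 3 at 1806 probe sets in Col, 2997 in Ler and 1179 in lfy-12, but at 378 in co-2 and 151 in ft-2. Some transcripts rose by day 3 and fell again by day 7, at 17 probe sets in Col, 127 in Ler, 258 in lfy-12, 3 in co-2 and 1 in ft-2. The opposite order, a fall and then a rise, was called at 18, 71, 34, 7 and 6 probe sets. Both steps share the day 3 arrays, so an error there gives either order, and no count expected by chance was computed. In Col these included AT3G62820 (1.11 ± 0.20 and then -1.98 ± 0.20) and BGLU45 (0.60 ± 0.14 and then -1.04 ± 0.14; SE, n = 2 arrays per day), and in Ler they included the sugar transporter gene SWEET14 (1.14 ± 0.22 and then -1.41 ± 0.22). More probe sets differed between mutant and wild type at day 7 than at day 0. At days 0, 3, 5 and 7 the counts were 844, 688, 2183 and 3837 for co-2, 649, 1070, 2575 and 4502 for ft-2, and 446, 453, 521 and 727 for lfy-12. Of these counts, only those between mutant and wild type at day 0 were repeated without single arrays. The rise of AT3G62820 in Col was not called without day 0 replicate 2 (0.91, adjusted p = 0.0735). The counts of co-2 at day 3 and of ft-2 at day 0 include an array with Columbia transcripts, and the 258 probe sets in lfy-12 rest on the day 0 arrays, of which replicate 2 lowered the day 3 total from 2388 to 708 when left out.

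The shortfall of rises in lfy-12 may arise after day 3. For the Ler risers, chosen on other arrays, the difference between lfy-12 and Col was -0.30 from day 3 to day 7 (fry adjusted p = 0.000367). It was -0.04 from day 0 to day 3, which did not pass the test and does not show that the genotypes were alike then. For the Ler fallers the difference was 0.40 from day 0 to day 7 and 0.06 when counted from day 3, so the fallers did not follow this timing.

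On 3 arrays, transcripts of the other background were present at a level that could come from a small amount of RNA or plants of the other accession. They were first seen with markers more than 8-fold apart, and were tested on separate, weaker markers. On lfy-12 day 5 replicate 2 the weaker markers gave a median share of 6.45%, with 13 of 14 above 2% (exact sign test p = 0.00183). On co-2 day 3 replicate 1 they gave 6.13%, with 39 of 46 above 2% (exact sign test p = 1.83e-06), and on ft-2 day 0 replicate 1 they gave 4.58%, with 32 of 46 above 2% (exact sign test p = 0.0114). The other 37 arrays lay between -4.52% and 2.04% by these markers. As an example, AOP3, which separates the accessions, stood at 4.49 and 6.17 on the lfy-12 day 5 arrays. Without these arrays the counts of called probe sets were 707 for lfy-12 at day 5, 132 for co-2 at day 3, 553, 1427 and 2456 for ft-2 at days 3, 5 and 7, and 247 for ft-2 against Ler at day 0. A segregating background or hybridization carryover between arrays was not tested.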
